A study of Mus musculus with 6 samples.

How the data were processed

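Total RNA of mouse pancreatic islets was sequenced in 6 libraries, 3 per diet. Per the labels' protocols, ribosomal RNA was removed and libraries were made with a stranded Illumina kit without poly(A) selection and read from both ends. Per the submitters' processing notes, the tools were TopHat2 2.0.8, Cufflinks 2.1.1, HTSeq 0.5.4p3 and edgeR on mouse genome build mm9, with no order or settings given in the sources used here. Whether the counting used strand is not given either.

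The authors deposited raw counts of reads for 39470 loci, a table of scaled values, and the assembled transcripts (98161) with coordinates in mm9. Each scaled value, a signal in the deposited table, is the count times 1 constant per library: after division by it, 100% of values were whole reads within 0.001 and equal to the raw counts. The 6 constants run from 0.906 to 1.10 and leave differences in depth in place. The count columns name the diets by abbreviations. ND was read as the normal diet and HDR, which the sources used here do not spell out, as the other diet. The mapping of HDR is therefore an inference from the names, and every statement of higher or lower, and every ranking of rises and falls, depends on it.

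The transcript file gives no gene symbols, and the reference annotation used here, GENCODE M21, is on another build. No coordinates were converted. A locus was linked to a reference gene when the ordered lengths of its exons and introns matched that gene's, each measured in its own build, and the symbol was then looked up by gene identifier. This is an inference from structure, not a name that the authors gave. Chains of introns and exons named 18198 loci. Of 18646 chain matches found without regard to position, 99.3% lay on the same chromosome and strand as the gene, and only those gave names. Shifted introns gave 74.75 matches on average, 3.5 of them on the same chromosome and strand. A rule for loci of 2 exons named 1589 more, with 48.25 matches (3.04%) for shifted introns, so a few of those names may be wrong. The 40-base tolerance at the ends of such loci was chosen after the ends of Ins1 had been seen to differ. Single-exon loci were not named, so that several islet genes are not analysed here by name. Named loci held 91.1% of counts. Of 585 genes in the fixed lists 543 were matched.

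Loci were classed as coding (20250), annotated long non-coding (3377), new (11809) or other non-coding (4034). The class came from the matched gene first and otherwise from the deposited file, an order chosen after Meg3 had been seen with a coding flag in that file; the flag alone gave 159 changed long non-coding genes, against 156. New loci were assembled from these same libraries, and 9260 of the 11809 have no strand and 9346 have 1 exon. Some match genes of the later annotation (157).

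Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Loci passing filterByExpr (23983) were normalised by TMM and tested with the quasi-likelihood test for diet alone, two-sided, with Benjamini-Hochberg adjustment over all loci tested and a threshold of 0.05. Values are TMM-normalised CPM. Each SE is the absolute log2 fold change divided by the square root of its quasi-likelihood F statistic. It was derived from the test and not estimated apart from it. The common dispersion was 0.0287. Gene lists with at least 3 tested members (28 of 29) were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. List medians were also set against 10000 draws of coding genes matched on mean CPM, a comparison that was not among those fixed beforehand. The comparison of diets, its test, the lists and the naming rule were fixed before the data were examined. Named are, among loci past the threshold with a mean of at least 1 CPM and high fat libraries all on one side of the normal diet libraries, the 10 coding genes, 5 long non-coding genes and 3 new loci with the largest change in each direction; up to 4 members of each list with the smallest adjusted p past the threshold; the hormone genes; and the 3 most abundant known long non-coding RNAs and markers of each cell type. Some items that the rule takes are not reported here. Of the 2591 loci past the threshold 2590 had no overlap between the diets, as did 39.2% of all loci tested, where chance gives 10% for 3 libraries against 3.

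The acinar share was compared by an exact permutation test. Fold changes of neighbours were compared by Spearman's rho with 100000 permutations. On simulated counts for 23983 loci with 200 changed by known folds, for the same 3 against 3 comparison, the test found 22.4% of 1.5-fold, 76.1% of 2-fold and 100% of 4-fold changes with the right sign, and 11 of 143 calls were false. All changed loci had a mean of at least 1 CPM. Median levels in the data were 0.98 CPM for long non-coding and 0.30 CPM for new loci, so these shares do not cover most new loci. Simulated loci vary independently, as real ones need not. The simulation changed only 200 loci, against 2591 called in the data. Under the Benjamini-Hochberg adjustment the share found depends on how many loci change, so it may differ in the data. At these depths (104657337 to 135353777 counts per library) 0 counts in a library allow up to 0.021 to 0.031 CPM, for counting error only. No such limit is given for loci whose exons lie in another locus. Alternatives were RLE factors, acinar genes left out of the scaling, no filter, DESeq2 1.42.0, edgeR's exact test, limma on the deposited scaled values with pseudocounts 1 and 0.1, a replicate block, an acinar covariate, a 1.5-fold minimum and each library left out. Cyclic loess with limma trend, limma trend on TMM values, scaled values over library totals, recovered reads and the removal of loci sharing at least 10% of exonic bases were added after seeing the data. Libraries of the same number were not taken as pairs.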

Results

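RNA was sequenced from pancreatic islets of C57BL/6 mice, an inbred laboratory strain, 14 weeks old at sacrifice after 8 weeks on a high fat diet or a normal diet. There were 3 libraries per diet. Islets are the hormone-secreting cell clusters of the pancreas, in which beta cells make insulin and alpha cells make glucagon. Ribosomal RNA was removed and no poly(A) selection was made, so that long non-coding RNAs without a tail were sequenced as well. Normal diet libraries 1, 2 and 3 held 113316088, 104657337 and 133633996 reads counted to loci, and high fat libraries 1, 2 and 3 held 121751015, 106332715 and 135353777. The labels do not say whether each library came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. High fat library 3 stood apart from the other high fat libraries on the second principal component, at 59.4 against -32.3 and -25.5.

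**Figure D1:**
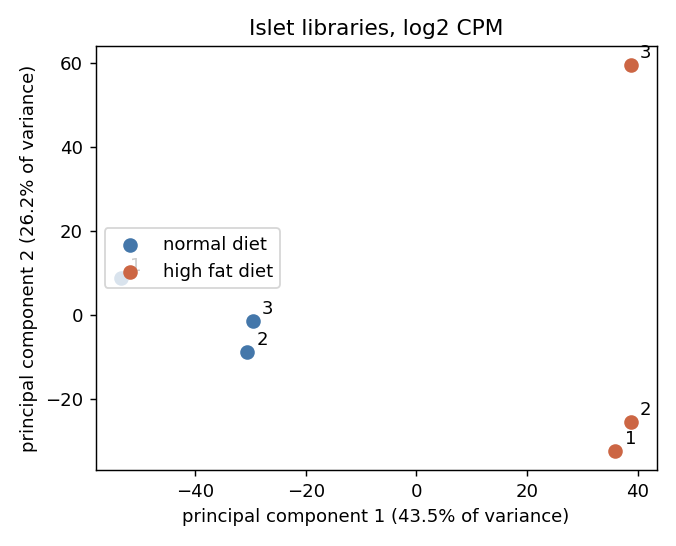
Principal components 1 and 2 (43.5% and 26.2% of the variance) of log2 CPM over 23983 loci, 1 point per library, with the library number beside it and colour giving the diet. The diets part on component 1, and high fat library 3 lies at 59.4 on component 2.

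The first comparison asked which genes differ in islets between the diets. Iapp, which encodes islet amyloid polypeptide, a peptide secreted with insulin, rose from 35729 ± 803 CPM to 58831 ± 5886 CPM (SD, n = 3 each), a log2 fold change of 0.72 (SE 0.094, edgeR adjusted p = 0.014). G6pc2, an islet glucose-6-phosphatase subunit, rose from 4398 ± 407 to 7559 ± 455 CPM, and the secretory granule protein gene Scg2 from 10971 ± 662 to 20044 ± 997 CPM. Of the genes that fell, Npy, which encodes neuropeptide Y, went from 11.4 ± 2.3 to 3.24 ± 2.0 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1426 of 23983 loci were higher and 1165 lower in high fat islets at an adjusted p of 0.05. These counts rested on every normal diet library. Without normal diet library 1, 2 or 3 the same test called 0 loci, with lowest adjusted p-values of 0.087, 0.055 and 0.083, while 5500, 6286 and 6294 loci had an unadjusted p under 0.05. Without high fat library 1 it called 94 higher and 34 lower, without high fat library 2 57 higher and 29 lower, and without high fat library 3 3075 higher and 1960 lower. With the acinar level of each library as a covariate it called 0 loci, against 5330 at an unadjusted p under 0.05, and DESeq2 without that covariate called 2476 higher and 1653 lower. Other settings turned the balance between higher and lower: 313 and 1024 with a 1.5-fold minimum, 1621 and 2075 by edgeR's exact test, 1134 and 1209 with no filter, and 399 and 945 by limma on the deposited scaled values, which keep differences in depth. Divided by library totals, the scaled values gave 1215 and 1141 by limma. A replicate block gave 54 and 20, and cyclic loess with limma trend 249 and 232.

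The protein-coding gene with the largest rise under the naming rule was Dapl1, at 32.9 ± 3.8 CPM on the normal diet and 141 ± 33 CPM on the high fat diet (4.29-fold, SE 0.17 on the log2 scale, edgeR adjusted p = 0.0074). It lies on chromosome 2 from 59322710 to 59343078 on the plus strand of mm9. Aldh1a3, an aldehyde dehydrogenase that makes retinoic acid, rose by 1.85 on the log2 scale, and Gucy2c, which encodes the guanylate cyclase C receptor, by 1.83 (41.3 ± 6.1 to 147 ± 22 CPM). Serpina7, Chil6, Inhba, Rasd2, Gc, Otoa and an unnamed coding locus (XLOC_016472) rose by between 1.60 and 1.78, the last by 2.26 without normal diet library 3. The largest falls were those of Cyp26b1, which degrades retinoic acid, at -3.93 (SE 0.81) from 2.69 ± 2.6 CPM, and Grp, which encodes gastrin-releasing peptide, at -3.87 (SE 0.51). Normal diet library 1 held 5.65 CPM of Cyp26b1 and the others 1.39 and 1.04. Without that library Cyp26b1 stood at -2.81 (adjusted p = 0.10), a smaller fall than that of Grp, and without high fat library 3 at -4.85. Htr3a, Npy, Lingo3, Nos1, Fam196a, Atf3, Fosb and Gpr22 fell by 1.35 to 1.83. The hormone genes other than Iapp did not pass the test. Ins1 had a log2 fold change of 0.32 (adjusted p = 0.12), with 61.6% of its exonic bases shared with another locus. Ins2, with 18.4% of its exonic bases shared, had 0.16 (adjusted p = 0.61), Gcg -0.29 (adjusted p = 0.080), Ppy -0.14 (adjusted p = 0.65) and Pyy -0.19 (adjusted p = 0.50). Over the 6 libraries Ins1 and Ins2 had means of 8391 and 13862 CPM, below the 47280 CPM of Iapp. Reads in the shared exons of Ins1 and Ins2 may not have been counted. These values therefore do not show whether insulin RNA changed. Sst was not named here.

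**Figure D2:**
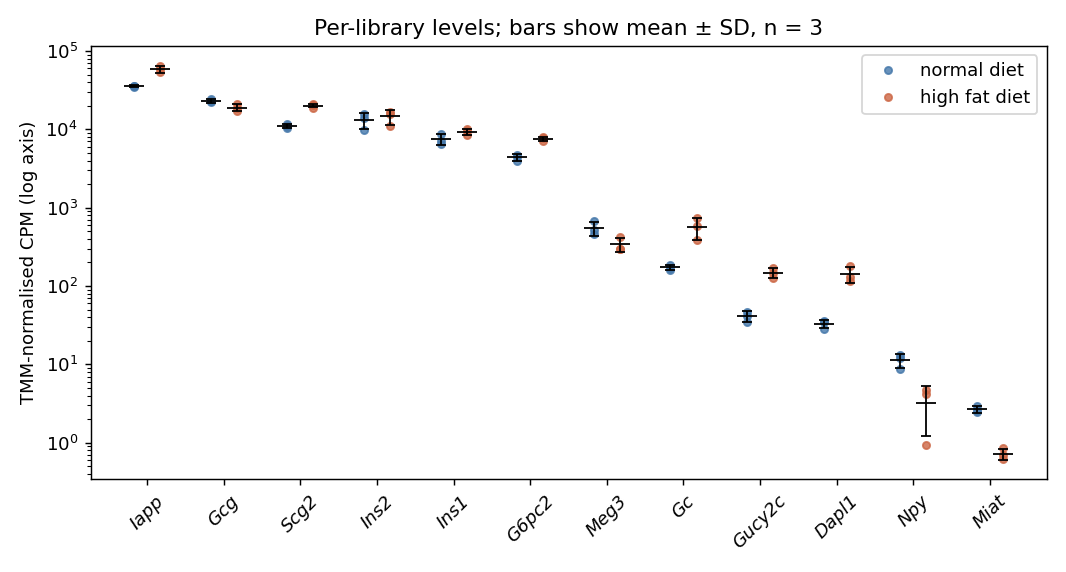
TMM-normalised CPM of 12 genes on a log axis, with 1 point per library and bars for the mean and SD of 3 libraries per diet. Iapp stood at 35729 CPM on the normal diet and 58831 on the high fat diet, while the Ins2 libraries of the diets overlapped. Ins1 and Ins2 share exonic bases with other loci, where reads may not have been counted.

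Gene lists fixed beforehand were tested with camera, which compares a list with all other genes. Of 28 lists, 11 passed with the preset correlation of 0.01, and 0 passed with an estimated correlation or with fry, where the lowest adjusted p-values were 0.48 and 0.052. Wrong splits of the 6 libraries passed up to 13 lists, so the calls below describe these libraries. Each median was also set against 10000 draws of coding genes of the same abundance. Of the lists that passed, all but the unfolded protein response lay at percentiles of 99.89 to 100 of the draws, or 0 to 0.72 where they fell. The draws took genes independently and leave out correlation within a list, which was estimated at 0.76 for the cell cycle and 0.87 for the acinar list. Such percentiles can therefore be extreme where a list moves together in a few libraries. In the cell cycle list 10 of 41 measured members rose and 0 fell (28 and 0 adjusted over the list alone), with a median log2 fold change of 0.82 (camera adjusted p = 2.5e-10, adjusted p = 0.48 with an estimated correlation). Bub1b, a mitotic checkpoint kinase, went from 3.57 ± 0.20 to 7.70 ± 2.4 CPM, and Rrm2, a ribonucleotide reductase subunit, from 4.84 ± 0.69 to 9.22 ± 1.9 CPM. High fat library 2 led the list at 0.82 above its mean over the libraries, against 0.27 and -0.12 in high fat libraries 1 and 3, and that library also had the largest acinar share. Without high fat library 2 the median was 0.45 and 0 members passed. Without high fat library 1 it was 0.89 and 0 passed, and without high fat library 3 it was 1.01 and 33 passed. Without normal diet library 1, 2 or 3 and with the acinar covariate it was 0.78, 0.79, 0.84 and 0.68, in fits that called 0 loci of any kind. In all of these fits the list passed camera with the preset correlation, at adjusted p-values up to 3.5e-09.

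Genes of secretory translocation, which carry new proteins into the endoplasmic reticulum, rose in 14 of 26 cases and fell in 0 (22 and 0 adjusted over the list alone; camera adjusted p = 4.4e-10, adjusted p = 0.48 with an estimated correlation), among them Ssr3, Ostc and Tram1 at 0.51, 0.51 and 0.50. In the unfolded protein response list 11 of 23 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 0.00023, adjusted p = 0.48 with an estimated correlation, and 0.55 under cyclic loess). Its median of 0.34 was at percentile 93.9 of coding genes of the same abundance, whose median was 0.26. The chaperone genes Dnajb11, Hspa5 and Hsp90b1 rose by 0.59, 0.47 and 0.45, and the transcription factor gene Atf3 fell by 1.48. Of the oxidative phosphorylation list 15 of 37 rose and 0 fell (21 and 0 adjusted over the list alone; camera adjusted p = 1.5e-08, adjusted p = 0.48 with an estimated correlation), with Ndufa4 at 0.59. Of fatty acid oxidation genes 7 of 22 rose and 0 fell (12 and 0 adjusted over the list alone; camera adjusted p = 2.3e-06, adjusted p = 0.48 with an estimated correlation). Cpt1a, which encodes an enzyme needed for long-chain fatty acids to enter the mitochondrion, rose from 40.7 ± 5.0 to 82.4 ± 6.0 CPM. Slc25a20 and Cd36 rose by 0.79 and 0.93. Of cholesterol synthesis genes 6 of 22 rose and 0 fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.00028, adjusted p = 0.48 with an estimated correlation), including Sqle at 0.41 and Msmo1 at 0.54.

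In the interferon response list 3 of 23 members fell and 0 rose (3 and 0 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.59 with an estimated correlation), namely Mx1, Oas2 and Irf7 at -0.97, -1.38 and -0.64. The list did not pass without normal diet library 3 (adjusted p = 0.074) or without high fat library 1 or 2 (0.086 and 0.071), nor on the deposited scaled values (0.083 and 0.080). Of the immediate early genes, which respond within minutes to stimulation or tissue handling, 3 of 10 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.48 with an estimated correlation). These were Fosb at -1.38, Dusp1 at -0.99 with 43.7% of its exonic bases shared, and Zfp36 at -0.61. The list did not pass without normal diet library 2 (adjusted p = 0.071), without high fat library 2 (0.062) or without loci sharing exonic bases (0.097). Of the beta-cell identity list 3 of 18 measured members rose (G6pc2, Iapp, and Pcsk1 at 0.36) and 1 fell (Isl1 at -0.62, with 46.0% of its exonic bases shared; 3 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.31). Its median was 0.070, its mean -0.0030 and its test pointed up. Under cyclic loess the list passed in the other direction, down (adjusted p = 0.048), and without loci sharing exonic bases it passed upward (0.035). The exocytosis list did not pass either (adjusted p = 0.075), with 5 of 23 higher and 2 lower, but it passed upward without normal diet library 2 (0.038), without high fat library 3 (0.0065) and with no filter (0.028). Coding genes of the same abundance rose more than either list, with medians of 0.25 against 0.070 for beta-cell identity (percentile 0.52) and 0.23 against 0.12 for exocytosis (percentile 1.64). In the beta-cell list Abcc8, Rfx6 and Slc6a6, with 96.6%, 95.3% and 94.3% of exonic bases shared, stood at -0.49, -0.50 and -0.65. Nkx2-2 and Ins1, with 68.7% and 61.6%, stood at 0.14 and 0.32, and the matched comparison was not repeated without such loci. The cytosolic ribosomal protein list (7 of 46 higher, 0 lower), antioxidant defence (3 of 15 higher, 0 lower), glycolysis (2 of 18 higher, 0 lower), beta-cell disallowed (1 of 15 higher, 0 lower), fatty acid synthesis (0 of 15 higher, 1 lower), inflammatory response (0 of 13 in either direction) and circadian clock (0 of 16 in either direction) did not pass, with camera adjusted p-values from 0.082 to 0.54. Without high fat library 3 the ribosomal protein and antioxidant lists passed upward (0.00012 and 0.038), as they did with no filter (0.028 and 0.042), and the ribosomal protein list did with the acinar covariate (0.038). Their medians were at percentiles 81.2 and 33.3 of coding genes of the same abundance. The fatty acid synthesis list passed downward under cyclic loess (0.0038), and its median and that of the circadian clock were at percentiles 0.01 and 0.17. Adjusted over the list alone, 7 exocytosis genes were higher and 2 lower, 9 and 3 of the ribosomal protein genes, 3 and 0 of antioxidant defence, 2 and 0 of glycolysis, 1 and 3 of the disallowed genes, and 0 in either direction of the last 3 lists.

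**Figure D3:**
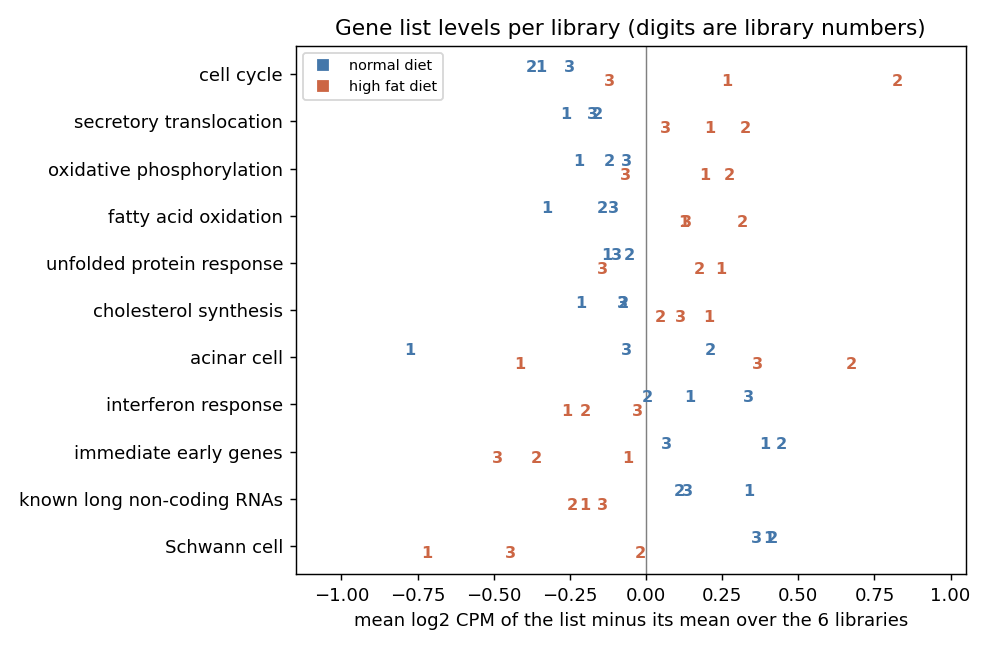
Mean log2 CPM of each of the 11 lists that passed camera with the preset correlation, minus its mean over the 6 libraries; digits are library numbers and colours the diets. High fat library 2 lies at 0.82 for the cell cycle list and at 0.68 for the acinar list.

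Markers of other cell types were measured in the same libraries. Acinar cells, which make digestive enzymes and surround the islets, took 0.715 ± 0.20% of counts on the normal diet and 0.958 ± 0.33% on the high fat diet (SD, n = 3; exact permutation p = 0.4, two-sided, where 0.1 is the smallest p possible). Of 27 acinar markers 1 rose, Try5 at 1.21, a member of the near-identical trypsin family. The acinar list passed camera (adjusted p = 0.0028, adjusted p = 0.70 with an estimated correlation), though not without normal diet library 1 (0.12) or high fat library 2 (0.074). With the acinar covariate it stood at 0.11, but that covariate is the mean level of these same markers. Adjusting for it takes out the list's own change, so no conclusion is drawn from that value. Of 7 alpha-cell markers 3 fell, Irx1 at -0.998, Irx2 at -0.53 and Slc7a2 at -0.46, and Gc rose by 1.71 (1 up and 5 down adjusted over the list alone), and the list did not pass (adjusted p = 0.17; 0.0056, downward, under cyclic loess). Its median of -0.46 lay below all draws of coding genes of the same abundance. Of 6 Schwann cell markers, the glia around islets, 3 fell, Sox10 at -1.43, Ngfr at -1.30 and Gfap at -1.13 (0 up and 3 down adjusted over the list alone; camera adjusted p = 0.037, adjusted p = 0.48 with an estimated correlation). That list did not pass without normal diet library 1, 2 or 3 (0.053, 0.074 and 0.062) or without high fat library 1 or 3 (0.072 and 0.080). Of 12 stromal markers Rgs5 and Acta2, pericyte and smooth muscle genes, rose by 0.69 and 0.83 and Thy1 fell by 0.998, with the list at an adjusted p of 0.61 and its median of -0.48 also below all draws. Csf1r fell by 0.50 among 11 myeloid markers (adjusted p of the list 0.11), and Fabp4 rose by 1.33 among 4 adipocyte markers (adjusted p of the list 0.75). Lists for delta, PP and epsilon cells, duct, endothelial and lymphocyte cells had 0 members past the test over all loci or adjusted over the list alone, with camera adjusted p-values of 0.10, 0.62, 0.41 and 0.41. The first of these passed downward without high fat library 3 (0.048) and under cyclic loess (0.035). The duct list had a median of 0.057, a mean of -0.16 and a test that pointed up. Adjusted over the list alone, 1 acinar marker was higher and 0 lower, 2 and 1 of the stromal, 0 and 2 of the myeloid and 1 and 1 of the adipocyte markers. The erythrocyte list had too few members for a test.

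The second comparison asked which known long non-coding RNAs differ. Of 1424 tested, 26 were higher and 130 lower in high fat islets. Miat fell from 2.67 ± 0.24 to 0.723 ± 0.11 CPM (log2 fold change -1.89, SE 0.18, edgeR adjusted p = 0.0090), and Meg3, an imprinted maternally expressed transcript, from 549 ± 108 to 340 ± 69 CPM (-0.69, SE 0.17, adjusted p = 0.039). Lrp8os2 fell by 1.28 and the unnamed loci XLOC_036830, XLOC_016478 and XLOC_034392 by 1.34, 1.24 and 1.23. The largest rises were those of 5830444B04Rik, Gm20754, Gm41177, Gm15747 and XLOC_004694, at 1.07, 1.049, 0.88, 0.78 and 0.73. In the fixed list of known long non-coding RNAs 2 of 15 fell and 0 rose (4 and 0 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.48 with an estimated correlation). It did not pass without normal diet library 1, 2 or 3 (0.16, 0.054 and 0.062), without high fat library 1 or 2 (0.072 and 0.062), with no filter (0.064) or on the deposited scaled values (0.067 and 0.068). Its other abundant members, 1700020I14Rik and Mirg, stood at -0.0063 and -0.36 and did not pass. Without normal diet library 1, 2 or 3, 0 long non-coding genes passed, without high fat library 1 or 2 there were 7 and 2, and without high fat library 3 there were 261. Against 156 with all libraries, 0 passed with the acinar covariate, 5 with the replicate block, 103 by limma on the deposited scaled values, 253 with DESeq2 and 263 by the exact test. Limma trend called 143 on TMM values and 38 after cyclic loess, which removes a trend with abundance.

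The third comparison concerned loci assembled from these reads that the submitters' file does not link to a known gene by the class codes =, j or o. Loci with other codes, such as i for a place within an intron of a known gene, count as new. Of 7998 tested, 175 were higher and 574 lower. The 7-exon locus XLOC_028544 on chromosome 6, from 49906652 to 49920291 on the plus strand, fell from 5.23 ± 0.77 to 1.21 ± 0.60 CPM (4.28-fold lower, SE 0.31 on the log2 scale, edgeR adjusted p = 0.018). It starts downstream of Npy, which lies from 49772728 to 49779504 on the same strand. XLOC_009563 and XLOC_035471 fell by 1.88 and 1.85. XLOC_008551, a 5-exon locus on chromosome 13 from 71865749 to 71993966, rose by 2.60 (SE 0.48), from 0.290 ± 0.071 to 1.76 ± 1.2 CPM, and by 1.86 without high fat library 2. XLOC_011192 and XLOC_000549 rose by 1.59 and 1.48. The first has code i, 1 exon and no strand, and its reads were not separated from those of the surrounding gene. The direction of change went with abundance in each class. Below 0.5 CPM the median log2 fold change was -0.36 for coding genes, -0.38 for known long non-coding RNAs and -0.41 for new loci, and above 32 CPM it was 0.17, 0.064 and 0.31. With limma trend in place of the quasi-likelihood test 714 new loci passed, against 749, and with cyclic loess, which removes the trend with abundance, before limma trend 138 did. Without normal diet library 1, 2 or 3, 0 new loci passed, without high fat library 1 or 2 there were 28 and 19, and without high fat library 3 there were 1173. With the acinar covariate 0 passed, with the replicate block 17, by limma on the deposited scaled values 498 and by the exact test 1297.

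**Figure D4:**
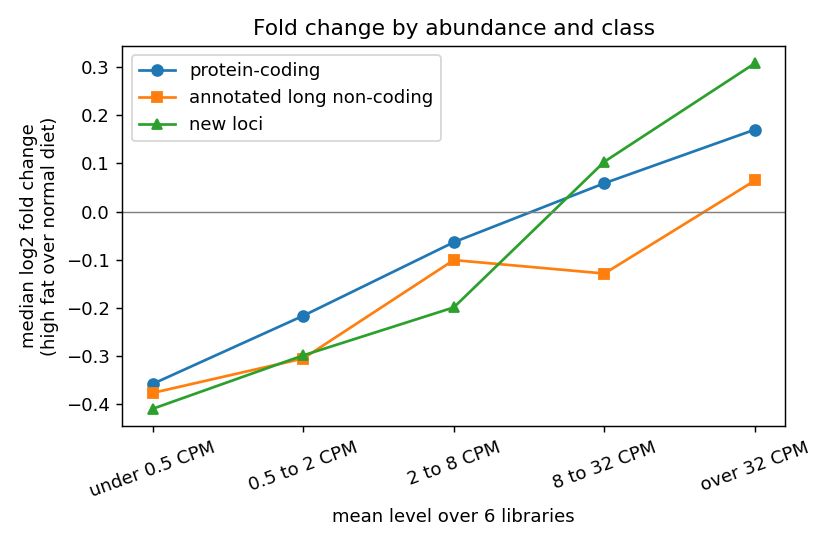
Median log2 fold change, high fat over normal diet, of protein-coding genes, annotated long non-coding genes and new loci in 5 ranges of mean CPM. The medians run from -0.36, -0.38 and -0.41 below 0.5 CPM to 0.17, 0.064 and 0.31 above 32 CPM.

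Fold changes of long non-coding or new loci and of their nearest coding gene were weakly correlated across 7742 pairs within 100000 bases (Spearman rho 0.13, permutation p = 1e-05, two-sided, the smallest that 100000 permutations can give). This is a correlation across genes, which are not independent replicates. New loci, whose coding potential was not tested, made up 6573 of the pairs. Neighbouring coding genes had a rho of 0.14 over 8815 pairs. Both members were past the threshold in 79 of the 7742 pairs, and in 34 of these they moved the same way. Of 140 such coding pairs 106 moved the same way. Changed new loci were mostly lower (574 against 175 higher) and changed coding genes mostly higher (1224 against 448 lower). The share expected from this was not worked out, so these counts do not show that neighbours oppose each other.

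Some genes that islets use could not be read from these counts. All 253 coding loci with every exonic base shared with another locus were at 0 in all 6 libraries, against 11.5% of 16041 coding loci that shared none. They included Slc2a2, the beta-cell glucose transporter, Gapdh and Ttr. Abcc8, a subunit of the beta-cell potassium channel, shared 96.6% of its exonic bases and had a mean of 24.5 counts, while a new locus across it on the other strand (XLOC_030893, chromosome 7, 53347078 to 53442244) had a mean of 34777. These genes were chosen after their values were seen.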

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

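Cyclic loess, limma trend, the removal of loci sharing exonic bases, recovered reads, scaled values over library totals and the class by coding flag were chosen after seeing the data; the other settings were planned. The counts of loci depended strongly on the libraries used. With 1 library left out, loci higher in high fat ran from 0 to 3075, loci lower from 0 to 1960, long non-coding genes from 0 to 261, new loci from 0 to 1173 and gene lists from 7 to 14; the zeros came without any 1 of the normal diet libraries, and the highest counts without high fat library 3. The lowest adjusted p in the fits that called 0 loci was 0.055 to 0.087, and 427 to 2209 loci passed at 0.1. With the acinar level as a covariate 0 higher, 0 lower, 0 long non-coding and 0 new loci passed (lowest adjusted p 0.062). With the replicate block 54 were higher, 20 lower, 5 long non-coding and 17 new, and 11 lists passed. Libraries of the same number deviated from their group means with correlations of -0.075, 0.075 and -0.014. Correlations between different numbers ran from -0.16 to 0.15, and not every library correlated best with its own number. These values give no sign of a pairing by number, but with 3 libraries per diet they cannot exclude one. DESeq2 called 2476 higher and 253 long non-coding genes, and edgeR's exact test 1621 higher and 2075 lower, 263 long non-coding and 1297 new. Limma on the deposited scaled values, which keep the depth, called 399 higher, 103 long non-coding and 498 new with pseudocount 1 and 407 higher with 0.1, and 70.3% and 70.7% of calls were lower, against 44.96%. A 1.5-fold minimum left 313 higher, with 76.6% of calls lower. Cyclic loess with limma trend called 249 higher, 232 lower, 38 long non-coding and 138 new, and moved the median log2 fold change by 0.10. Limma trend on TMM values, without the loess, called 1341 higher, 1116 lower, 143 long non-coding and 714 new. The main fit called 1426, 1165, 156 and 749, so the test alone lowered the counts only a little. Without loci sharing exonic bases 950 were higher. Camera with an estimated correlation and fry passed 0 lists. Otherwise the cause was not tested. Other settings kept the counts within 1.5 times. The acinar share kept its direction, from 0.11 to 0.43 points, as did the neighbour correlation, from 0.12 to 0.20.

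Of the 2591 loci called in the main fit, 2 had the opposite sign under cyclic loess with limma trend. Named genes that did not pass changed sign in some settings. Under cyclic loess Ins1 stood at -0.089, Ins2 at -0.28, Krt8 at -0.18, Tspan8 at -0.053, Kdr at -0.15, Flt1 at -0.11 and Cd22 at 0.094. 1700020I14Rik stood at 0.013 with RLE, 0.038 with DESeq2 and 0.026 with limma on scaled values at both pseudocounts. Krt8 stood at -0.0082 on scaled values over library totals, Kdr at -0.023 with the acinar covariate and Plvap at 0.018 with DESeq2. With 1 library left out Ppy ran from -0.32 to 0.075, Ins2 from -0.028 to 0.33, 1700020I14Rik from -0.075 to 0.040, Krt8 from -0.097 to 0.30, Tspan8 from -0.044 to 0.22, Kdr from -0.089 to 0.19, Flt1 from -0.075 to 0.14 and Plvap from -0.20 to 0.22. Lists that turned under cyclic loess had adjusted p-values of 0.048 for beta-cell identity, which passed downward, 0.21 for exocytosis, 0.85 for glycolysis, 0.66 for endothelial and adipocyte and 0.95 for lymphocyte. The adipocyte list also turned without a filter, at 0.73. With 1 library left out the adjusted p ran from 0.18 to 0.93 for beta-cell disallowed, from 0.10 to 0.84 for lymphocyte and from 0.60 to 0.97 for adipocyte.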

Other observations

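The tests on abundance, exocrine carry-over, a single library and shared exons were chosen after the result was seen; those on receptor loci and on other splits were written before. The test on changed loci without shared exons was written before its value was seen, but the removal of those loci was itself chosen after the overlap had been seen. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1426 higher and 1165 lower loci, 156 long non-coding genes and 749 new loci, and the highest of the other splits gave 0 of each, so that 1 of 10 splits reached each of these counts. The real split passed 11 gene lists and another split 13, so that 2 of 10 splits passed as many. That other split set normal diet libraries 1 and 3 and high fat library 3 against the rest.

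Changed loci outside the coding class were mostly lower in high fat islets, and changed coding genes mostly higher, 1224 against 448. The coding part does not hold with a 1.5-fold minimum, where 231 coding genes were higher and 340 lower. Shared exons do not account for the falls outside the coding class as a whole, since 79.8% of the changed long non-coding and new loci were lower after loci sharing exonic bases had been left out. A dependence of fold change on abundance may contribute. Without matching, median log2 fold changes were -0.25 for long non-coding genes, -0.34 for new loci and 0.061 for coding genes. Against coding genes matched on level, the long non-coding and new loci together stood at -0.083, so matching narrowed the gap. The bootstrap interval over loci, which are not independent replicates, was -0.10 to -0.064, close to the bound of 0.1 set for it. More reads spread over the genome in normal diet libraries also stays open, as the summed CPM of 171 olfactory and vomeronasal receptor loci had a log2 ratio of -0.34, but normal diet library 2, at 10.5 CPM, lay below high fat library 3, at 11.2. The diet itself was not separated from these.

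Of 41 cell cycle genes 10 passed as higher in high fat islets and 0 as lower. The list passed camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.48) or with fry (0.14). With the acinar level as a covariate their median log2 fold change was 0.68 (interval over members 0.56 to 0.77) against 0.82 without, and without high fat library 2 it was 0.45 (0.36 to 0.56). Neither value passed the bound set for it by more than its interval. The intervals treat genes as independent, though their correlation was estimated at 0.76, and do not measure the spread between libraries. The tests therefore cannot decide, and exocrine carry-over and a single library stay open as partial causes, beside the diet.

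Genes at or near 0 whose exons lie in another locus may be low because reads in exons shared with another locus were not counted: 100% of coding loci with every exonic base shared were at 0. That islets do not express them is argued against by 5 cytosolic ribosomal protein genes, used by every cell, that share every exonic base and were at 0. Whether strand was used in the counting was not tested. Shared bases were taken on either strand, and loci with no strand held counts. Among these were XLOC_011192 with 881 counts over the 6 libraries, XLOC_009563 with 959 and XLOC_035471 with 1110. These counts argue against a count by strand, at least for such loci, so reads may not be separated between loci on opposite strands.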
